A study of Caenorhabditis elegans with 5 samples.

How the data were processed

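Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an anti-GFP antibody on L2 larvae of the *Caenorhabditis elegans* strain OP37, per the labels' protocols. The strain carries an integrated transgene, wgIs37, that encodes PHA-4 fused to a TY1, EGFP and 3xFLAG tag and also carries unc-119(+), in an unc-119(ed3) background. Hermaphrodites were grown at 20 °C and fixed with 2% formaldehyde, which was quenched with 100 mM Tris, per the labels' protocols. The 5 libraries fall into 3 immunoprecipitations and 2 inputs. Of the immunoprecipitations, 1 is labelled replicate 1 and 2, from separate extractions, are labelled replicate 2; both inputs are labelled replicate 1. The labels do not say whether the replicates came from separate cultures, so overlap between the lists may reflect technical repeats.

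The values analysed were 3 lists of enriched regions that the authors deposited: replicate 1, replicate 2 and both replicates combined. Each region has a start, an end and a PeakSeq q-value, and its coordinates are on WormBase WS190, per the file headers and fields. PeakSeq scores the tags of an immunoprecipitation against those of a control, so a q-value ranks the evidence for enrichment and is not a level of binding. The highest q-value in any deposited list was 0.00998. The aligner, the PeakSeq version and settings, the input used for each list and the way the replicates were combined are not given in the sources used here. The lists carry no read counts and no signal, so the sequencing depth is unknown, no library could be compared with another, and q-values were used to rank, filter and compare regions within a list and, as scores, to relate regions that overlapped between lists.

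Overlap meant at least 1 shared base pair. The score of a region was −log10 of its deposited q-value. Coordinates are 1-based and inclusive. Chromosome lengths were taken as the furthest region end in any list, 100177638 bp over 6 chromosomes, because no sequence or annotation of WS190 was used. Overlap counts from the code matched those of bedtools 2.31.1 for every pair of lists tested. Shares have 95% exact Clopper-Pearson intervals, which cover counting error only. The share of a replicate list that overlapped the other list was set against 10000 circular shifts of that list within each chromosome, a one-sided permutation test. Correlations and differences in medians were tested with 100000 permutations, two-sided; these run across regions, which are not independent replicates. Shares per chromosome were tested with two-sided exact binomial tests that assume independent regions. Fisher's exact test, used for X against the autosomes, makes the same assumption. Where regions cluster, those p-values are too small, so the share in the central part of the chromosomes, and its difference between X and the autosomes, were also set against 10000 rotations of each chromosome. With chromosomes as the units, the smallest permutation p for a single chromosome of 6 is 0.167. The 11 main tests form 1 family for Benjamini-Hochberg adjustment, and the adjusted values for single chromosomes were taken over the 6 chromosomes of a list. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. The overlap code was tested on simulated data in which an overlap of 60% was built in. Of 4011 simulated regions 61.5% overlapped, against 62.0% expected once chance overlap, estimated with the same shifts, was added. Unrelated lists overlapped in 5.21% of regions with a shift estimate of 4.98%. Simulated regions were placed evenly at random along each chromosome, whereas the deposited regions were concentrated in the middle. The simulation therefore does not show how well the shifts estimate chance overlap for clustered lists.

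The main tests other than that of the chromosome I share, the alternatives and the rule for named regions were fixed before the data were examined. Of the shares of single chromosomes, only that of X had a planned test. The rule named the 15 combined regions with the lowest q-values by position where no gene positions of the same build were at hand; regions named outside it were chosen after their values were seen. The alternatives fixed at that point were a reciprocal overlap of 50%, midpoints within 200 bp, stricter q-values, lists of equal length, merging of regions within 500 bp and leaving out each replicate. Shifts of 10000 to 100000 bp, lists without regions under 100 bp, without chromosome I or without a block on chromosome V, and combined regions present in both replicate lists were added later. Planned counts by annotation class, tests on 32 gene lists, motif content and gene coverage need a genome or annotation of WS190 and were not run. The gene table at hand is for another assembly, and neither its coordinates nor its names were used.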

Results

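PHA-4, a FoxA transcription factor that specifies pharyngeal identity in *C. elegans*, was profiled as a GFP fusion in L2 larvae to locate the regions it binds. The data consisted of 3 immunoprecipitations and 2 inputs, summarised by the authors in 3 lists of enriched regions. The replicate 1 list held 4077 regions with a median width of 381 bp (interquartile range 306 to 529), covering 1.94% of the 100177638 bp spanned. The replicate 2 list held 5335 regions with a median of 352 bp (264 to 485.5) and covered 2.27%. The combined list held 7745 regions with a median of 360 bp (262 to 505) and covered 3.39%. Widths ran from 1 bp to 9135 bp over the lists, and 520 combined regions (6.71%) were under 100 bp. Sequencing depth is unknown, as the lists give positions and q-values only. The q-values are the authors' own, and all coordinates are on WS190.

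The strongest PHA-4::GFP regions of the combined list lay on 5 of the 6 chromosomes. This ranking leaves out a stretch of chromosome V, 20740660 to 20774524, in which the combined list used here held 0 regions, although it held the regions at places 1, 2 and 5 of replicate 1 and at places 2 and 5 of replicate 2. The lowest combined q, 7.26e-193, belonged to a region of 2733 bp on chromosome X, at 16929310 to 16932042. It was followed by chromosome I, 9379948 to 9384173 (q 9.48e-178), chromosome V, 6357861 to 6360581 (q 4.64e-151), chromosome X, 6844003 to 6846470 (q 8.85e-130), and chromosome III, 8799765 to 8802653 (q 1.63e-128). The 15 best combined regions comprised 4 on X, 3 each on I, IV and V, 2 on III and 0 on II. They were 707 to 4459 bp wide with a median of 2721 bp, against 360 bp for the whole combined list. Each of these 15 regions overlapped a region in both replicate lists, which are not independent of a list that combines both replicates. Their places differed between replicates: the best region on X stood at place 1 in replicate 2 (q 9.58e-171) and at place 53 in replicate 1 (q 7.22e-35), whereas the region at 6844003 on X stood at place 7 in replicate 2 and place 9 in replicate 1. The region at 6357861 on V stood at place 4 in replicate 1 and place 6 in replicate 2. Other regions stood further down in both replicate lists. The region at 12198707 on IV stood at place 32 in replicate 1 and 96 in replicate 2. That at 9379948 on I stood at places 18 and 68. It overlapped 3 replicate 1 regions and 2 replicate 2 regions, and the region on IV overlapped 2 in each list. Each place given for them is that of 1 of these replicate regions. Regions picked as the best of 1 list tend to rank lower in others. Given both replicate scores, combined scores were also higher on chromosome I (median residual 3.33 over regions present in all lists) than on the other chromosomes. The combined ranking may therefore favour regions on I. The genes at these positions were not analysed here.

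The first comparison asked how far the regions found in one replicate were found in the other. Of the replicate 1 regions, 3236 of 4077 (79.4%, 95% exact interval 78.1 to 80.6) overlapped a replicate 2 region. In the other direction 3252 of 5335 (61.0%, 59.6 to 62.3) overlapped. Shifted lists overlapped in 4.77% and 3.67% of regions on average, so each observed share was 16.6 times that of chance. This ratio depends on the rule for overlap: for replicate 1 it was 57.7 with a reciprocal overlap of 50%, 33.9 with midpoints within 200 bp and 42.8 when only the best-scored 1019 replicate 1 and 1334 replicate 2 regions were compared, as chance overlap fell. No shift reached the observed share in either direction (permutation p = 0.0001 each, the smallest that 10000 shifts can give, adjusted p = 0.00011). The difference between the 2 directions goes with the length of the lists. With replicate 2 cut to its 4077 best-scored regions, 71.8% of replicate 1 and 72.0% of replicate 2 regions overlapped. Of the 50 best replicate 1 regions, 50 were present in replicate 2. Of the 50 best replicate 2 regions, 48 were present in replicate 1.

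Overlap fell with the strength of the region. With each list divided into 4 equal groups by q, 98.5% of the strongest replicate 1 regions overlapped replicate 2, followed by 89.9%, 71.9% and 57.2% of the weakest. For replicate 2 the corresponding shares were 96.0%, 74.4%, 47.8% and 25.7%. The lists held 4077 and 5335 regions, so lower shares in replicate 2 do not show that its regions were less reproducible. Replicate 1 regions found in both lists had a median q of 7.09e-06 and a median width of 397.5 bp, against 0.0017 and 325 bp for the 841 regions found in replicate 1 alone. In replicate 2 the medians were 1.23e-06 and 401 bp for shared regions and 0.00168 and 276 bp for the 2083 others. The differences in median score (2.38 in replicate 1 and 3.14 in replicate 2) and in median width (72.5 bp and 125 bp) each had a permutation p of 1e-05, the smallest that 100000 permutations can give, and an adjusted p of 1.375e-05.

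**Figure D1:**
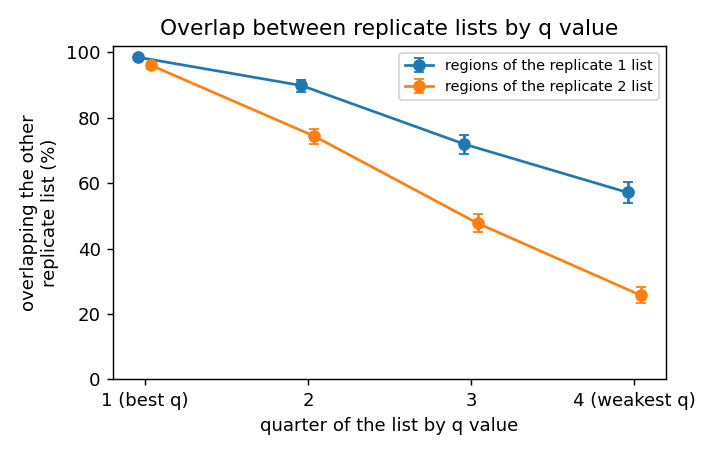
Share of the regions of each replicate list that overlapped the other list, in percent, for 4 equal groups ordered from the strongest to the weakest q, with 95% exact intervals. The share fell from 98.5% to 57.2% in replicate 1 and from 96.0% to 25.7% in replicate 2.

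Regions found in both replicates also resembled each other in score. Over 3206 pairs of regions matched by longest overlap, Spearman's rho between the scores was 0.644 and Pearson's r was 0.725 (permutation p = 1e-05 for each, the smallest possible, adjusted p = 1.375e-05). This correlation runs across regions, which are not independent replicates. Both inputs are labelled replicate 1 and the input behind each list is not given in the sources used here, so the lists may share a control, which can itself raise their overlap and the correlation of their scores; neither the shifts nor the permutations account for this. Matched regions had median widths of 397 bp in replicate 1 and 401 bp in replicate 2.

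Some strong regions appeared in 1 replicate list only; those given here were chosen after their values were seen. In the strongest group, 15 replicate 1 regions (1.47%) and 53 replicate 2 regions (3.97%) had no partner. The strongest were on chromosome V at 1803866 to 1806374, the region at place 3 of replicate 2 (q 3.02e-81), and on chromosome III at 9050964 to 9055004, at place 9 (q 6.99e-56). In replicate 1 the strongest was on chromosome II at 9225381 to 9227466, at place 131 (q 6.42e-25). All 15 and all 53 overlapped a combined region, where the region on V had place 101 (q 9.70e-53) and that on III place 341 (q 2.98e-32).

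The second comparison set the combined list against the replicates. Of the 7745 combined regions, 3191 (41.2%, exact interval 40.1 to 42.3) overlapped both replicate lists, 794 (10.3%) replicate 1 alone, 1766 (22.8%) replicate 2 alone and 1994 (25.7%, 24.8 to 26.7) neither. Regions present in both replicates were the strongest and widest, with a median q of 5.09e-13 and a median width of 476 bp. Those present in neither had a median q of 0.00248 and a median width of 233 bp, and 420 of them (21.1%) were under 100 bp. In the best-scored 3872 combined regions, 78.6% overlapped both replicate lists and 0.956% neither. At the 3191 regions present in all lists, the combined q was lower than both replicate q-values in 3175 (99.5%), and the median score was 12.3 in the combined list, 5.15 in replicate 1 and 5.94 in replicate 2.

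Nearly all replicate regions were retained in the combined list: 4028 of 4077 (98.8%) from replicate 1 and 5037 of 5335 (94.4%) from replicate 2. A stretch on chromosome V, 20740660 to 20774524, stood apart; it was singled out after its values were seen. In this stretch of 33865 bp, 7 replicate 1 regions covered 47.9% of the sequence and 5 replicate 2 regions covered 75.9%. They included the region with the lowest q of replicate 1 (20754893 to 20757987, q 6.08e-116) and the second lowest of replicate 2 (20755495 to 20760421, q 4.22e-152). The combined list used here held 0 regions in it. Outside this stretch, the lowest q of a replicate region absent from the combined list was 6.40e-06 in replicate 1 and 9.74e-05 in replicate 2. The stretch was delimited as the span of the strong replicate regions absent from the combined list, so none of those could lie outside it.

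**Figure D2:**
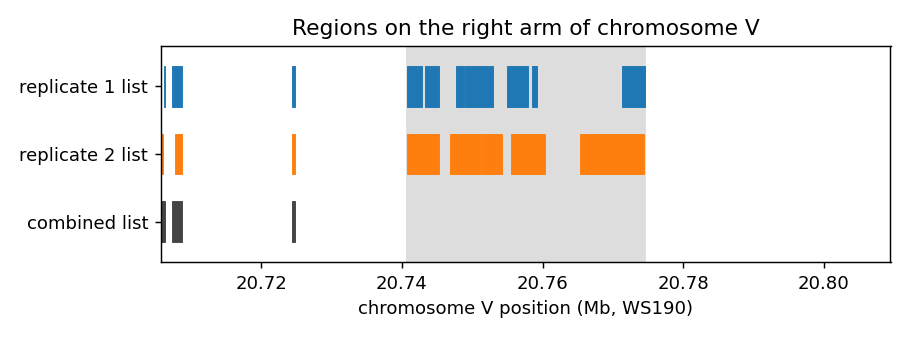
Regions of the replicate 1, replicate 2 and combined lists along chromosome V around 20740660 to 20774524 (shaded; WS190, position in Mb on the horizontal axis, 1 track per list). Both replicate lists covered much of this stretch, 47.9% and 75.9%, and the combined list had 0 regions in it.

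The last comparison asked how the combined regions were spread over the chromosomes. The X chromosome held 1395 regions, 18.01% of the total (exact interval 17.2 to 18.9), against 17.7% of the length, a difference that did not pass the test (exact binomial p = 0.448, adjusted p = 0.448). Chromosome I, for which no test had been planned, held 1657 regions, 21.4% (20.5 to 22.3) against 15.01% of the length (exact binomial p = 1.26e-50, adjusted p = 6.92e-50). Its density was 110 regions per Mb, against 64.8 on V, 68.5 on IV, 70.5 on II, 77.2 on III and 78.7 on X. Chromosome V held a lower share than its length, 17.5% against 20.9% (exact binomial p adjusted over 6 chromosomes 3.24e-13), as did IV, 15.5% against 17.5% (6.93e-06), and II, 13.9% against 15.2% (0.00135). Shares sum to the whole, so the excess on I lowers the others. In the replicate lists V stayed below its length share, whereas II did not pass the exact test in replicate 1 (adjusted p = 0.257) or replicate 2 (0.196), and IV passed it in replicate 1 (adjusted exact p = 0.0334) but not in replicate 2 (0.0949). Among the combined regions present in both replicates neither II (adjusted exact p = 0.127) nor IV (0.157) passed. In the replicate lists chromosome I held 17.9% (replicate 1) and 18.4% (replicate 2) of regions, and 18.5% of the combined regions present in both replicates. The share of chromosome I was 30.7% among combined regions present in neither replicate list. In the best-scored 3872 combined regions it was 23.5% (22.1 to 24.8). That ranking uses combined scores, which were higher on chromosome I than the replicate scores predicted. This share is therefore not separate support for an excess on I among strong regions. The result for X depended on the regions used: the X share was 16.7% in the best-scored 3872 combined regions (exact p = 0.114), where that of chromosome I was higher. Outside chromosome I the X share was 22.9% against 20.8% of the length (exact p = 6.05e-05).

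**Figure D3:**
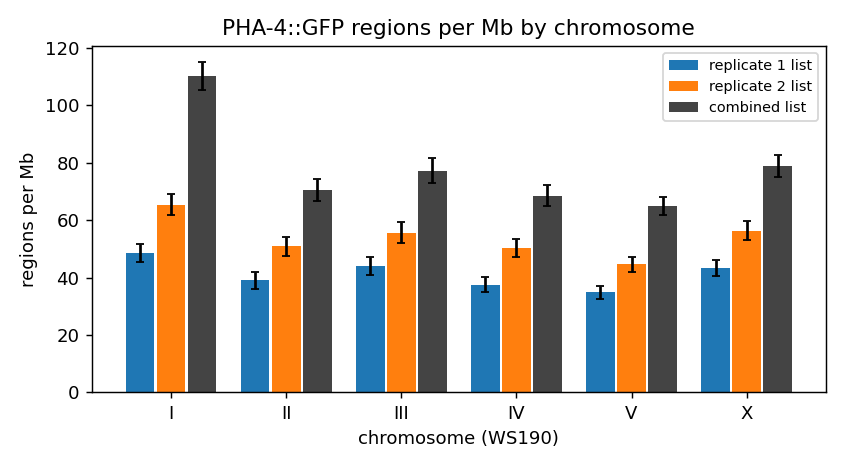
Regions per Mb on each of the 6 chromosomes in the replicate 1, replicate 2 and combined lists, with error bars for the 95% exact interval of each share. In the combined list chromosome I stood at 110 regions per Mb and the other chromosomes between 64.8 and 78.7.

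Along the chromosomes, regions were concentrated in the middle. With each chromosome divided into 3 equal parts, the middle part held 3254 combined regions, 42.0% (exact interval 40.9 to 43.1) against 33.3% of the length (exact binomial p = 5.61e-57, adjusted p = 6.17e-56). Rotated chromosomes gave 33.3% on average and 41.9% at most (permutation p = 0.0001, the smallest that 10000 rotations can give). The concentration was greatest on V, where 47.5% of regions lay in the middle part. On X the share was 35.1% (32.5 to 37.6), against 43.5% (42.3 to 44.8) over the autosomes, which ranged from 38.9% (36.0 to 42.0) on III to the 47.5% on V. The intervals of III and X overlapped. In replicate 1 the share on X was 33.9% against 45.2% over the autosomes and 40.2% on III, and in replicate 2 it was 35.6% against 44.0% and 39.3%. X had the lowest share of the 6 chromosomes in each list. The difference between X and the autosomes was set against rotations of each chromosome, which keep the spacing of regions. The two-sided permutation p was 0.026 in the combined list, 0.016 in replicate 1 and 0.024 in replicate 2. The adjusted permutation p was 0.026 for each of the 3 lists. These rotations model chromosomes with no concentration in the middle, which the combined list as a whole already exceeded. The p-values therefore do not show that X departs from the autosomes by more than autosomes differ among themselves. Fisher's exact test, which treats regions as independent, gave a far smaller p for the combined list (4.98e-09), and with chromosomes as the units the smallest permutation p for 1 chromosome of 6 is 0.167. The comparison of X with the autosomes was added after the data were seen.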

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

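The alternatives that left out regions under 100 bp, chromosome I or the chromosome V block, used shifts of 10000 to 100000 bp, or kept combined regions present in both replicate lists were chosen after the data were seen. Of 58 alternatives, 50 kept the direction and the side of the threshold, or stayed within the interval, of the value reported. The share of combined regions present in both replicate lists went from 41.2% to 36.5% with a reciprocal overlap of 50%, 78.6% in the best-scored 3872 regions and 43.7% without regions under 100 bp; the share present in neither went from 25.7% to 29.1%, 0.956% and 22.6%. These moves follow from a stricter rule, from leaving out weak regions and from leaving out short ones, since 420 of the 520 combined regions under 100 bp were present in neither list. The X share reversed to 16.7%, below its 17.7% of the length, in the best-scored 3872 regions (exact p = 0.114). In those regions chromosome I held 23.5%, against 21.4% of the whole list. That rise lowers the shares of the other chromosomes but accounts for only part of the fall on X. Outside chromosome I the X share passed the threshold at 22.9% (exact p = 6.05e-05), against 20.8% of the length, as regions on I no longer entered the total. Leaving out a replicate meant using the deposited list of the other, as no combined list could be remade, so these 6 of the 50 repeat values of the replicate lists: the X share was 18.7% to 18.8%, that of chromosome I 17.9% to 18.4% and that of the middle part 42.4% to 43.0%. Overlap, score agreement, strength and composition need both replicate lists and gave no value with 1 left out. No paired analysis was possible because the immunoprecipitations and inputs share only replicate number 1 and the lists hold no values per library. Annotation class, gene list enrichment, motif content and gene coverage were not run, nor were their alternatives, and 0 q-values were tied, so the alternative for ties did not apply. Unknown depth limits any reading of regions missed in 1 list.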

Other observations

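The windows of dense regions, the tests on the chromosome V block, the test of a looser threshold on chromosome I, the fit within the weaker regions and the test of widths of unmatched regions were chosen only after the result was seen. In windows of 35000 bp, the combined list covered most on chromosome II, 10525001 to 10560000, with 16352 bp in 9 regions; in the same window the replicate 1 list covered 9308 bp and the replicate 2 list 11099 bp. The next were chromosome V, 6210001 to 6245000, with 12515 bp in 8 regions, chromosome IV, 14590001 to 14625000, with 12298 bp in 10 regions, and 6720001 to 6755000 on X with 11570 bp in 8 regions. The median window held 825 bp. The window on V contained the region at 6225685 to 6230143, the widest of the 15 best at 4459 bp.

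The block on chromosome V, 20740660 to 20774524, held strong regions in both replicate lists and 0 in the combined list used here. The regions of the block were neither weak nor one-sided, as both replicate lists held regions there, all with q-values of 3.97e-08 or lower. All 2315 other replicate regions with a q at or below that of the weakest block region overlapped a combined region (100%, exact interval from 99.8%). The block was delimited as the span of the strong replicate regions absent from the combined list. This share could therefore not have been lower, and it decides nothing about loss on combining. Extra copies of a stretch of genomic DNA, such as a transgene, stay open as a candidate explanation of the strong regions in both replicate lists. They would not by themselves account for the absence of regions from the combined list. The transgene carries pha-4, a gene of chromosome V, whose position relative to the block was not tested. Coverage in the flanking 35000 bp was at most 12.4% of that inside, but the edges were set at the outermost of these strong regions and their density had been seen, so this value decides nothing, and dense binding at a locus of normal copy number would give it too. No biological explanation was tested, and what set the combined list apart here was not tested either.

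Chromosome I held 613 of the 1994 combined regions present in neither replicate list (30.7%, exact interval 28.7 to 32.8). A looser threshold on every chromosome is argued against, because chromosome I held only 17.9% (15.6 to 20.4) of the weakest regions of replicate 1 and 17.1% (15.1 to 19.2) of those of replicate 2, taking the weakest of 4 equal groups. Scoring of chromosome I that was more favourable in the combined list may explain the excess: at the 3191 regions present in all lists, the combined score given both replicate scores had a median residual of 3.33 on chromosome I (bootstrap interval 3.16 to 3.53), which lay 3.61 above the highest of the other 5 chromosomes, whose medians spanned 0.714. Among the weaker of these regions the median was 2.52 on chromosome I and -0.0263 on V, the next highest. Why the scores differed was not tested, nor was any biological explanation.

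Strong regions without a partner in the other replicate, such as those at 1803866 on V and 9050964 on III, were few. Shifted or split boundaries are argued against, since at most 6.67% of the unmatched strongest regions in either list lay within 500 bp of a region of the other list. Whether they reflect broad enrichment seen in 1 replicate cannot be told apart from chance: unmatched regions were wider by 50 bp in replicate 2 (permutation p = 0.2), and in replicate 1 the difference in median width was -8 bp (permutation p = 0.92), with 53 and 15 unmatched regions. No biological explanation was tested.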
